A study of Mus musculus with 8 samples.

How the data were processed

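Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into DNA that is not protected by nucleosomes or other proteins, so that open regions yield more fragments. The 8 samples were mouse embryonic stem cells of a line with a doxycycline-repressed Cdx2 transgene, sampled on days 0, 3, 4 and 5 of differentiation after doxycycline withdrawal, either as control (labelled wild type) or with Alkbh1 overexpression. Each of the 8 groups held 1 library. Peak lists were used for the 2 day 5 libraries, and the other 6 samples were not analysed here. No label ties libraries to separate cultures. A test of the condition with the days as blocks would need peak lists of the other days, so no p-value compares the groups.

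The submitters' processing notes name Bowtie2 2.3.1, MACS2 2.1.1, deepTools and the mouse genome build mm9, without their roles. Per the peak names in the deposited files, peaks were called on paired-end fragments, without a fragment model and with a q-value threshold of 0.05, separately in each library. The smallest −log10 q in the deposited lists was 1.30 in both. The deposited fold values are ratios of the signal at the summit to the local background, and the deposited −log10 p and −log10 q values belong to the same summit. The deposited score is 10 times −log10 q cut to a whole number, except in 1 control row. The use of an input library, the removal of duplicates and the effective genome size are not given in the sources used here. Peak ends on chromosome 1 reached position 197108609, beyond the end of the last gene on that chromosome in the GRCm38 gene table. Coordinates are therefore given in mm9, counted from 1, and the GRCm38 table was not used to place genes. Without an mm9 annotation, peaks could not be assigned to genes, exons, introns or promoters, so Alkbh1 itself and the planned gene lists and promoter shares are not reported.

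The peak caller's fold and −log10 p were used to recover the depth behind each peak. If fold equals (pileup + 1)/(background + 1) and p is the upper Poisson tail of the pileup, both unknowns follow from the 2 deposited values. A whole-number pileup met both values within 0.001 in −log10 p for 100% of the rows in both lists, with a largest misfit of 0.000204. The next best whole number missed by at least 0.00212. On simulated values of the same precision, 100% of 48205 simulated control rows and 100% of 4456 simulated overexpression rows were recovered. Among 1000 simulated rows per list made with another fold formula, 0.3% and 0.6% passed the tolerance. The pileup is the number of fragments over the summit. The smallest background in a list is taken as the library background, the mean fragment coverage that the caller assumed for the whole genome. Comparing it between the lists requires the same genome size and the same handling of duplicates in both calls. Mean coverage also counts mitochondrial fragments and grows with fragment length. Neither the mitochondrial share nor the fragment lengths are known here.

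Peaks on chromosomes 1 to 19, X and Y were analysed, which left out 9 control and 6 overexpression peaks on mitochondrial DNA. No interval was listed more than once. Peaks counted as shared with an overlap of at least 1 bp. The overlap code gave the same count as bedtools 2.31.1, and it recovered 100% of 200 planted overlaps of 1 bp. The chance level of overlap is the mean of 100 random placements of the overexpression peaks on their own chromosomes. Shares have exact (Clopper-Pearson) 95% binomial intervals and pileups exact 95% Poisson intervals, and the interval of a pileup ratio comes from the exact binomial split of both pileups. Intervals of medians in the closing observations come from 1000 resamples of the peaks and describe the spread among peaks. The other intervals and the limits cover counting error only. No interval covers variation between libraries. Peaks are not replicates, and fragments without molecular identifiers are not independent molecules. Where a control peak overlapped several overexpression peaks, the one with the highest pileup was taken. For a peak listed in one library only, the pileup was set against the other library's calling limit, the largest pileup that its own list's smallest called −log10 p left uncalled at the same local background, scaled by the ratio of the library backgrounds. The limit leaves out the caller's minimum peak width and is no bound for a narrower region. Where medians cover control peaks without a partner, the missing partner was ranked below all called values.

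Regions were named by a rule set before the data were examined: the 5 strongest peaks by −log10 p in each library, the 5 strongest found in the control alone and the 5 strongest found in overexpression alone. The alternatives planned at the same time were a q-value of 1e-5 or less, a fold of 5 or more, stricter overlap rules, all sequences, other measures of strength, the equally long strongest part of the control list, and the control scaled to the background of the overexpression library. Windows of raised control background are the 88 windows of 1 Mb with at least 10 control peaks whose median local background was at least 1.5 times the library background. The 1 Mb windows, the local background classes and the alternatives that use them were chosen after the data had been seen. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.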

Results

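The series followed chromatin accessibility while embryonic stem cells were driven by Cdx2, a transcription factor of the trophectoderm lineage, towards trophoblast-like cells, with and without overexpression of Alkbh1, a dioxygenase of the AlkB family studied as a demethylase of N6-methyladenine in DNA. The question addressed at day 5 was which accessible regions of the control cells were also accessible in cells that overexpressed Alkbh1. The control library had 48196 peaks on the nuclear chromosomes, covering 18.4 Mb, and the overexpression library had 4450 peaks, covering 1.28 Mb. The background coverage assumed by the peak caller was 2.21 fragments per position in the control and 2.29 in the overexpression library. The ratio of 1.04 stands for equal depth only if both lists were called with the same genome size and handling of duplicates. The mitochondrial share of fragments and the fragment lengths would also have to be alike. Each condition had 1 library with a peak list, so the differences compare these libraries and have no replicate check.

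Called peaks were far fewer and narrower in the Alkbh1 overexpression library. The control list held 10.8 times as many peaks and covered 14.3 times the length. The median peak width was 302 bp in the control (quartiles 197 and 490 bp) and 232 bp in overexpression (quartiles 173 and 340 bp). Peaks of 1000 bp or more numbered 1387 in the control and 40 in overexpression, a ratio of 34.7. Among peaks that were called, the summits had similar heights, with a median pileup of 16 fragments (quartiles 13 and 22) in the control and 17 fragments (quartiles 14 and 22) in overexpression. The median fold enrichment was 4.67 in the control and 4.55 in overexpression. At the library background, the largest pileup left uncalled was 8 fragments in the control and 10 fragments in overexpression.

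The overexpression peaks lay almost entirely within the control set. Of the 4450 overexpression peaks, 4136 overlapped a control peak, a share of 92.9% (95% interval 92.2 to 93.7%), whereas random placement gave 1.24% on average and 1.64% at most. In the other direction, 4042 of the 48196 control peaks overlapped an overexpression peak, a share of 8.39% (8.14 to 8.64%) against 0.115% by random placement. Of the overexpression peaks, 50.6% (49.1 to 52.1%) overlapped one of the 4450 strongest control peaks. The share expected for an evenly weaker copy of the control library, with counting error, was not computed. Whether the list differs from the strong end of the control list was therefore not tested. When at least 50% of both peaks had to overlap, the share of overexpression peaks with a control partner was 33.6%, as the control peaks were the wider ones.

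Control regions that were also called under overexpression were broader and stronger at the median than those that were not, though many broad and strong control peaks were not called. Shared control peaks had a median width of 654 bp (quartiles 436 and 885 bp) and a median pileup of 33 fragments (quartiles 25 and 42). The 44154 peaks found in the control alone had a median width of 285 bp (quartiles 191 and 450 bp) and a median pileup of 15 fragments (quartiles 12 and 20). With the control peaks split by −log10 p into 10 classes of equal size, the shared proportion was 0.892% (0.646 to 1.20%) in the weakest class and 47.3% (45.8 to 48.7%) in the strongest. By width, it was 1.78% (1.55 to 2.02%) for control peaks under 200 bp and 20.5% (19.7 to 21.3%) from 500 to under 1000 bp. It was 47.3% (44.7 to 50.04%) for the 1356 control peaks from 1000 to under 2000 bp. For the 31 control peaks of 2000 bp or more it was 93.5% (78.6 to 99.2%). The median control pileup rose with width, from 12 fragments under 200 bp to 38 at 2000 bp or more. Width and height were therefore not separated here, and a wide peak meets a 1 bp overlap more easily.

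**Figure D1:**
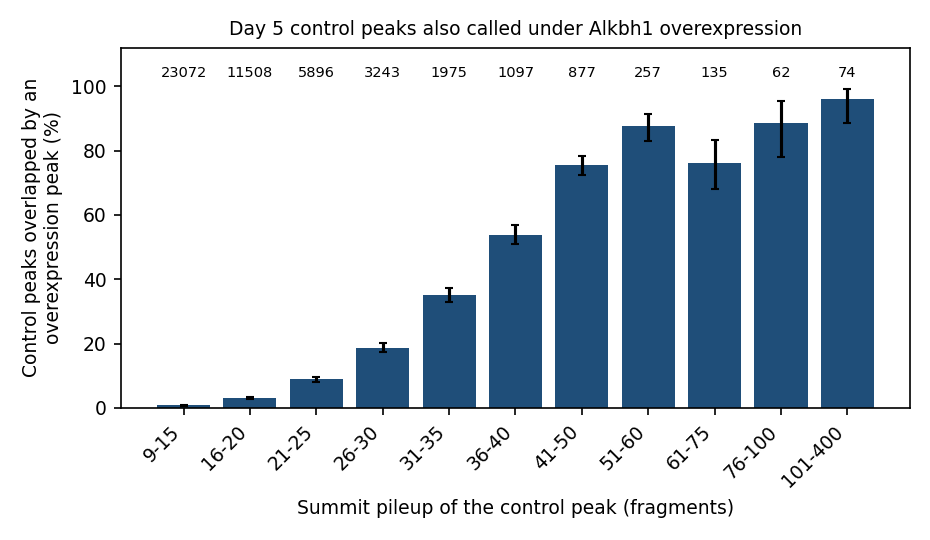
Share of day 5 control peaks overlapped by an overexpression peak (y axis, percent) in classes of control summit pileup (x axis, fragments); bars are shares, error bars exact 95% binomial intervals and the numbers above the bars count the control peaks in each class. The share is 0.754% at pileups of 9 to 15 and 95.9% above 100.

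Summit pileups at control peaks were lower in the overexpression library, and the height of the control peak alone did not set by how much. At the 4042 shared control peaks, the median ratio of overexpression to control pileup was 0.533 (quartiles 0.424 and 0.833). The pileup was lower in overexpression at 3404 of them (84.2%), higher at 562 and equal at 76. This ratio is an upper estimate, because only peaks above the calling limit enter it. For the 877 control peaks with pileups of 41 to 50 fragments, of which 75.5% were shared, the median overexpression pileup with uncalled peaks ranked lowest was 17 fragments, or 0.375 of the control. For the 74 control peaks with pileups above 100 fragments, 95.9% (88.6 to 99.2%) were shared and the median ratio was 0.882. Looked at from the other list, overexpression peaks with pileups of 16 to 20 fragments had a median control pileup 1.94 times as high, and those with 41 to 50 fragments one 0.939 times as high.

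Few tall control peaks had a pileup ratio from 0.5 to under 0.75. The classes of ratio were of unequal width and were not planned, and whether the ratios form separate bands was not tested. Of the 1405 control peaks with at least 41 fragments, 684 (48.7%, 46.0 to 51.3%) had an overexpression pileup under 0.5 times the control, 121 (8.61%, 7.20 to 10.2%) had a ratio from 0.5 to under 0.75, and 311 (22.1%, 19.99 to 24.4%) had a ratio of 0.75 or more. The remaining 289 (20.6%, 18.5 to 22.8%) had no overexpression peak, with a median width of 576 bp (quartiles 326 and 828 bp) and a local background 2.29 times the library background at the median. Peaks with a ratio under 0.5 were broad, with a median width of 838 bp (quartiles 678 and 1041 bp), and their local background was 1.78 times the library background at the median. Peaks with a ratio of 0.75 or more were narrower, with a median width of 459 bp (quartiles 302 and 709 bp), and their local background was 6.19 times the library background at the median. The calling limit rises with the local background, so at a high background a low ratio could go uncalled. Part of the link between ratio and background may follow from this. If no input library was used, the local background also holds the peak's own fragments. The median control pileup was 46 fragments at ratios under 0.5, 48 from 0.5 to under 0.75 and 61 at 0.75 or more. Of these 311 peaks, 144 (46.3%) lay in the 10 windows of 1 Mb with the most overexpression peaks. So did 14 (11.6%) of those from 0.5 to under 0.75, 5 (0.731%) of those under 0.5 and 49 (17.0%) of those without an overexpression peak. The windows were picked for overexpression peaks, which any ratio requires, so part of the concentration follows from the choice.

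**Figure D2:**
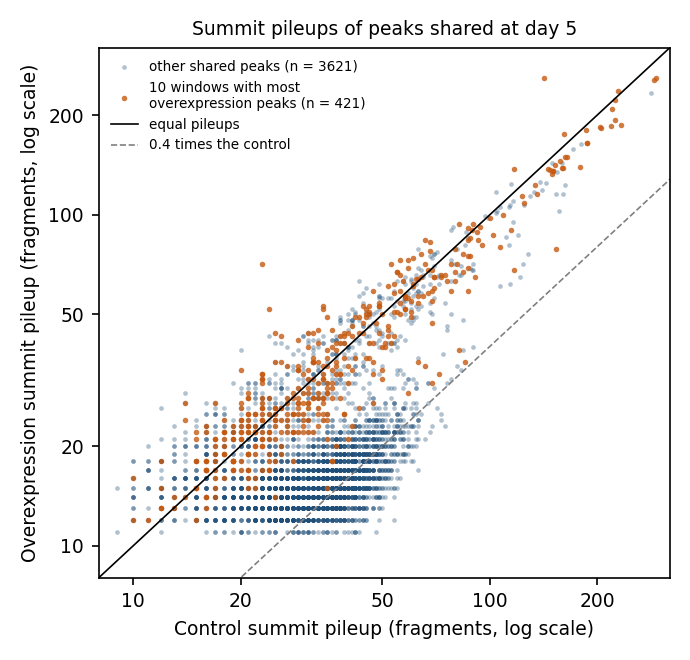
Summit pileup of shared day 5 peaks in the control (x axis, fragments, log scale) against the overexpression library (y axis, fragments, log scale), 1 point per shared control peak; the solid line marks equal pileups, the dashed line 0.4 times the control, and orange marks the 421 shared peaks in the 10 windows of 1 Mb with the most overexpression peaks. Some points follow the line of equal pileups and others lie below it, with few points between them at high control pileups.

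The 5 strongest regions of each list were called in both libraries, with pileup ratios of overexpression to control from 0.720 to 0.924. The strongest peak of either list was on chromosome 9 at 35112799 to 35113176 in the control and 35112802 to 35113176 in overexpression, with 171 fragments (146 to 199) and 158 fragments (134 to 185), a ratio of 0.924 (0.740 to 1.15). Second in both lists was a region of chromosome 2, at 98506397 to 98507486 in the control, with 284 fragments (252 to 319) in the control and 234 fragments (205 to 266) in overexpression. Its ratio was 0.824 (0.690 to 0.983). The region of chromosome 16 at 57391241 to 57391799 had 161 fragments in the control and 116 in overexpression, a ratio of 0.720 (0.563 to 0.920). The region of chromosome 12 at 98299641 to 98300002 had 153 and 116 fragments, a ratio of 0.758 (0.590 to 0.971). Near the distal end of chromosome 18, at 90771575 to 90772027, the pileup was 144 fragments in the control and 125 in overexpression, a ratio of 0.868 (0.678 to 1.11). The other 2 regions among the 5 strongest of the overexpression list were on chromosome 9, at 123370928 to 123371306 with a ratio of 0.913 (0.711 to 1.17) and at 3000007 to 3002811 with a ratio of 0.887 (0.748 to 1.05). The intervals of the ratios lay below 1 for the regions of chromosomes 2, 16 and 12 and included 1 for the others. The regions of chromosomes 16 and 12 were named by the control list only. Picking by strength in the control tends to lower a ratio, and picking by strength in overexpression tends to raise it. The intervals take no account of this choice. All these regions had a raised local background in the list that named them. It was 29.6 at the chromosome 2 region in the control and 38.3 at 3000007 on chromosome 9 in overexpression. At the others it was 4.71 to 5.78, against library backgrounds of 2.21 and 2.29. If the peaks were called without an input library, a tall peak raises its own local background. These values therefore need not describe the surroundings of the peaks. No region was left out for repeated sequence, and extra genome copies were not tested here.

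The strongest control peaks without an overexpression peak stood several-fold above the calling limit of the overexpression library. This limit is the largest pileup that the p-value threshold left uncalled at the same local background. It takes no account of width, and no overexpression peak was narrower than 134 bp and no control peak narrower than 132 bp, so a narrower region with more fragments could go unlisted. The strongest control peak without an overexpression peak was on chromosome 13 at 113368385 to 113368527, with 55 fragments (41.4 to 71.6) against a limit of 10 fragments in overexpression, 5.50 times as many. On chromosome 6, the region at 146803617 to 146804040 had 53 fragments and the region at 128580013 to 128580584 had 45 fragments in the control, 4.82 and 4.50 times the limit. The regions at 18533285 to 18533418 on chromosome 16 and 79826121 to 79826772 on chromosome 14 had 48 and 52 fragments, 4.80 and 4.33 times the limit. With widths of 143 and 134 bp, the regions of chromosomes 13 and 16 were close to the narrowest called peaks. Over all 44154 control-only peaks, 8038 (18.2%) had at least 2 times the limit and 856 at least 3 times. At 4217 of them (9.55%), the control pileup itself lay at or under the limit, so no loss was detectable there at this calling limit. The limit assumes that the local background keeps its multiple of the library background in overexpression. Where that multiple was lower, the limit is too high. The smallest called −log10 p was 4.59 in overexpression and 3.47 in the control.

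In the overexpression library alone, 314 peaks were found, and they were narrow. Their median width was 171 bp (quartiles 149 and 216 bp) and their median pileup 16 fragments (quartiles 13 and 21). None had a pileup of 3 times the control's calling limit or more, 40 (12.7%) had at least 2 times the limit, and 228 (72.6%) at least 1.5 times, against 20248 (45.9%) of the control-only peaks at 1.5 times the overexpression limit or more. The last 2 shares start from unlike floors. At the library background the limit was 8 fragments in the control and 10 in overexpression. At or under the other library's limit lay 4217 control-only peaks and no overexpression-only peak, so the shares cannot be compared. The strongest was on chromosome X at 120811049 to 120811184, with 26 fragments (17.0 to 38.1) against a limit of 9 in the control, 2.89 times as many. Next came chromosome X at 121274845 to 121275020 with 37 fragments, 2.47 times the limit, and at 166441205 to 166441448 with 84 fragments, 1.75 times the limit on a local background of 29.9. A region at 53239639 to 53239883 of chromosome X had 25 fragments and a region at 14386281 to 14386419 of chromosome 15 had 21 fragments, 2.78 and 2.63 times the limit. Of the 314 peaks, 99 (31.5%) lay within 1000 bp of a control peak.

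The overexpression peaks were spread unevenly over the chromosomes. Chromosome X held 7.98% (7.20 to 8.81%) of the overexpression peaks and 3.45% (3.29 to 3.61%) of the control peaks. Chromosome 14 held 7.96% (7.18 to 8.79%) and 4.83% (4.64 to 5.03%), and chromosome Y 1.15% (0.854 to 1.504%) and 0.149% (0.117 to 0.188%). Chromosome 7 was also higher, at 7.35% (6.599 to 8.15%) against 6.30% (6.09 to 6.52%). The shares of chromosomes 2, 3, 10, 11, 15 and 19 were lower in overexpression, with intervals apart from those of the control, and the intervals of the other 11 chromosomes overlapped. Against the 4450 strongest control peaks, X, 14 and Y remained higher and no chromosome was lower.

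**Figure D3:**
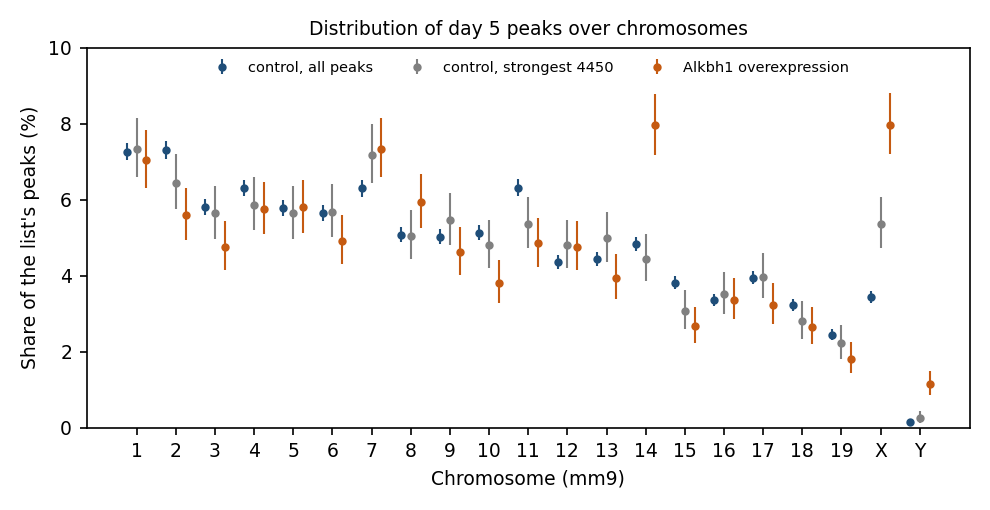
Share of the peaks in each list that lies on each mm9 chromosome (y axis, percent); points are shares and bars exact 95% binomial intervals for all control peaks, the 4450 strongest control peaks and the overexpression peaks. Chromosomes 14, X and Y have overexpression shares of 7.96%, 7.98% and 1.15%, above both control sets.

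Part of the excess on these chromosomes lay in a few megabases with many overexpression peaks. Without the 1 Mb windows of raised control background, the shares of overexpression and control peaks were 3.22% (2.66 to 3.87%) and 2.90% (2.75 to 3.06%) on X, with overlapping intervals. They were 5.14% (4.43 to 5.93%) and 4.06% (3.88 to 4.25%) on 14, and 0.291% (0.139 to 0.534%) and 0.0568% (0.0367 to 0.0838%) on Y, where 10 overexpression and 25 control peaks were left. Windows of 1 Mb were examined after the chromosome shares had been seen and were picked for their number of overexpression peaks, so a higher shared proportion in them follows in large part from the choice. Pileup ratios of windows cover shared peaks only. A higher local background raises the calling limit, so control peaks with a low ratio could be missing from them. The median window with any overexpression peak held 2 of them. Positions 120000001 to 123000000 of chromosome X held 230 overexpression and 358 control peaks. There, 55.9% (50.6 to 61.1%) of control peaks were shared, with a median pileup ratio of 1.00 (quartiles 0.875 and 1.13). Elsewhere on X, 8.60% (7.13 to 10.3%) of control peaks were shared, the median ratio was 0.519, and the region outside the run held 2.81% of all overexpression and 2.70% of all control peaks. Positions 3000001 to 9000000 of chromosome 14 held 171 overexpression and 510 control peaks, with 24.1% (20.5 to 28.1%) shared and a median ratio of 0.967, against 9.19% (7.90 to 10.6%) and 0.515 on the rest of the chromosome. The window from 2000001 to 3000000 on chromosome Y held 41 overexpression and 47 control peaks, with a median ratio of 0.966. Windows from 19000001 on chromosome 8, from 3000001 on chromosome 9, from 146000001 on chromosome 4 and from 15000001 on chromosome 5 held 54, 31, 31 and 31 overexpression peaks, with median ratios of 0.917, 0.901, 0.879 and 0.931. The 10 windows with the most overexpression peaks held 11.1% of all overexpression peaks and 1.95% of control peaks, and over all other windows the share of control peaks kept was 7.66% (7.42 to 7.91%), with quartiles of the pileup ratio at 0.414 and 0.720.

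**Figure D4:**
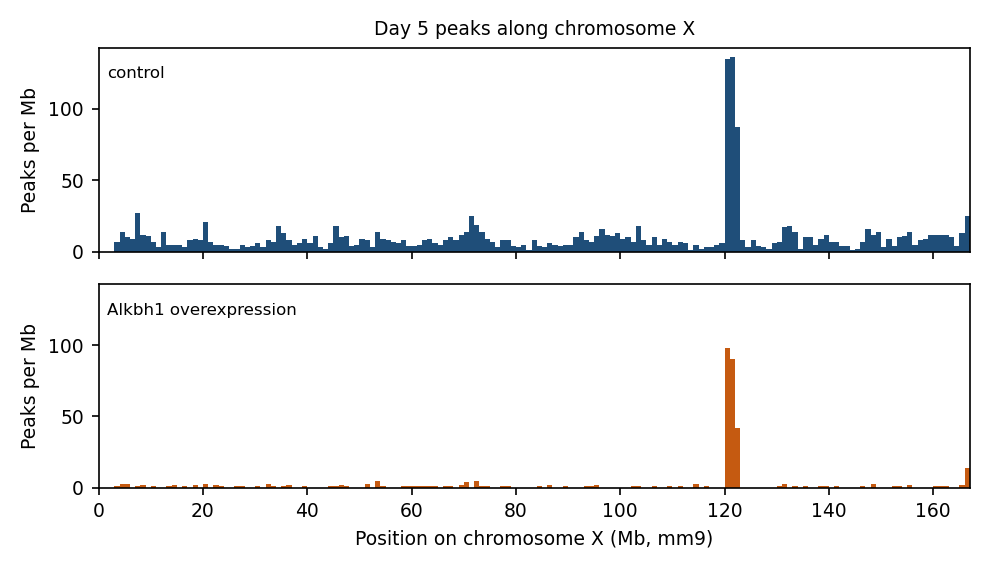
Number of day 5 peaks per 1 Mb window (y axis) along chromosome X in mm9 (x axis, Mb), control above and Alkbh1 overexpression below, on the same scale. The 3 windows from 120 to 123 Mb hold 358 control and 230 overexpression peaks, while the rest of the chromosome holds 1303 and 125.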

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

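The alternatives without the windows of raised background and by pileup were chosen after seeing the data. With a q-value of 1e-5 or less, 27594 control and 1939 overexpression peaks were left, and with a fold of 5 or more 18498 and 1414, so the control list stayed the longer one. The share of overexpression peaks that overlapped a control peak was 91.6% when the overlap had to reach 50% of the shorter peak, 33.6% at 50% of both peaks, 91.1% for overexpression summits inside a control peak and 50.6% against the equally long strongest part of the control list. It was 94.8% without the 1 Mb windows of raised control background. The share of control peaks that overlapped an overexpression peak was 3.10% at 50% of both peaks, 6.79% for control summits inside an overexpression peak, 6.47% at a q-value of 1e-5 or less in both lists, 9.11% after the control was scaled to the overexpression background, and 7.24% without the windows of raised background. The strongest of the 10 classes of control peaks was shared to 40.4% by fold enrichment, 35.4% by width and 51.6% by pileup. Shared control peaks were 2.29 times as wide as control-only peaks at the median, and 1.43 times with 50% of both peaks required; the smaller value follows from that rule, which excludes broad control peaks over narrow overexpression peaks. The number of chromosomes whose shares lay apart was 10 in all, 3 against the strongest control peaks and 5 without the windows of raised background. Those 5 were 7, 12, 14 and Y, higher in overexpression, and 11, lower. Without those windows the overexpression and control shares were 3.22% and 2.90% on X, 5.14% and 4.06% on 14, and 0.291% and 0.0568% on Y. Except where the rule itself gives the reason, the cause was not tested. Promoter shares and gene lists were planned and not run, for want of an mm9 annotation. No paired analysis was possible because peak lists were used for the day 5 pair alone. At the smallest −log10 p called in each list, a region at the library background needed more than 8 fragments in the control and 10 in overexpression.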

Other observations

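All tests of explanations in this part were chosen after the results they bear on had been seen. Peak edges coincided in a small class of shared regions. At 136 of the 4042 shared control peaks (3.36%), both edges lay within 10 bp of those of the overexpression peak, and the median pileup ratio was 0.979 against 0.520 at the others. A peak with fewer fragments tends to be called narrower, so coinciding edges in part select for equal pileups. Among the 71 shared control peaks with more than 100 fragments, 35.2% had such edges, and the ratio was 0.882 with them and 0.887 without. At 100 fragments or less, it was 1.07 with them and 0.519 without. Outside the windows of raised background, tall control peaks (at least 41 fragments) narrower than 400 bp kept at least 0.8 of their pileup at 41 of 94 peaks (43.6%, 33.4 to 54.2%), against 61 of 895 (6.82%, 5.25 to 8.67%) for those of 400 bp or more. The narrower ones were less often called in overexpression, at 67 of 94 (71.3%, 61.02 to 80.1%) against 747 of 895 (83.5%, 80.9 to 85.8%). Mitochondrial DNA had 9 peaks in the control and 6 in overexpression.

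The first pattern is that the overexpression library had fewer peaks. The tables argue against the stricter p-value threshold that the caller reached in the overexpression list, because 46151 control peaks passed that same threshold. Lower depth of the overexpression library stays open. Its library background was 1.04 times that of the control. This would exclude lower depth only with the same genome size and handling of duplicates in both calls, and neither is stated. The background also counts mitochondrial fragments and grows with fragment length, so it does not settle the nuclear depth. Also open are weaker enrichment over background in this library preparation, with a median pileup ratio of 0.386 (0.378 to 0.391) at tall control peaks outside the windows of raised background, and an effect of Alkbh1 overexpression on accessibility. The last 2 cannot be told apart, since 1 overexpression library at day 5 has a peak list here and condition and library are confounded. A broad loss of accessibility and a diluted signal would both lower most broad peaks by a similar factor.

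The second pattern is that pileups at shared peaks were nearly equal in the 10 windows of 1 Mb with the most overexpression peaks. The median ratio at the 421 shared peaks was 0.947. These were 44.7% of the 942 control peaks there, and the others had no called overexpression pileup. A raised local background lifts the calling limit, so lower pileups could have gone uncalled. Equality is therefore not shown for the windows as a whole. A candidate explanation is sequence present in more genome copies than the assembly holds, which would add fragments in proportion to copies rather than to accessibility. The local background at these peaks was 2.75 times the library background in the control, and the overexpression multiple was 0.973 (0.962 to 0.980) of the control multiple. At 1741 shared peaks elsewhere, picked for a raised control background, the overexpression multiple was 0.696 (0.687 to 0.707) of the control multiple and the median pileup ratio 0.472, so in both sets the background ratio was low or high with the pileup ratio. These values do not decide for extra copies. The windows were picked for their overexpression peaks, and if the peaks were called without an input library, the local background holds the same fragments as the pileup, so similar pileups bring similar backgrounds. Extra copies and accessibility kept there under Alkbh1 overexpression cannot be told apart, since the ratio of 0.947 would follow from either and neither an input library nor a second library per condition was at hand.

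The explanation by genome copies was first tested on another set of windows, where the outcome was mixed, and the test on the 10 windows took its place after that outcome was known. The first set was the 88 windows with at least 10 control peaks that had a median local background of at least 1.5 times the library background. There, 20.5% (19.3 to 21.8%) of control peaks were shared, against 7.24% (6.997 to 7.48%) in the other windows. Among tall control peaks the order was the reverse, with 302 of 416 shared (72.6%) against 814 of 989 (82.3%). The median pileup ratio at tall control peaks was 0.574 (0.480 to 0.748) there, between that of the other windows and equality. Uncalled peaks ranked lowest in this median, and a raised background lifts the calling limit. Calling may therefore have lowered both the shared proportion and the ratio of tall peaks there. These values do not decide whether a raised background marks regions of equal pileup. In 39 windows that were as dense in control peaks without a raised background, 8.96% (7.72 to 10.3%) of control peaks were shared.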
